A study of Arabidopsis thaliana with 20 samples.

How the data were processed

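Expression was measured with an array in total RNA of Arabidopsis thaliana, in 20 samples, 10 labelled wild type (WT, ecotype Columbia-0) and 10 labelled atpc1-1, all grown on MS medium per the labels. The deposited values are intensities on a linear scale, with 1 column per sample and 3439 rows. How the authors made these intensities, including the array's background correction, scaling and any filter, is not given in the sources used here. From the values alone, column means lie between 0.920 and 1.06, no value is negative, and no value exceeds 100. The ceiling of 100 was reached only in atpc1-1 columns, by 3 rows with no gene listed, 1 of them in all 10 atpc1-1 columns, so the difference of those rows is limited by the ceiling. A value of 0 was read as a row with no measured signal, not as a level.

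Precision is limited by the number of arrays and by signal near the floor. Median intensity per column ranged from 0.339 to 0.493 in WT and from 0.130 to 0.224 in atpc1-1. In WT columns 3.63% to 4.36% of rows stood at 0, against 5.70% to 20.8% in atpc1-1. The 50 brightest rows held 24.7% to 31.8% of the summed intensity in WT columns and 44.0% to 49.7% in atpc1-1 columns.

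Duplicate columns were looked for before genotypes were compared, by correlating deviations from the genotype mean between columns of the same genotype. In both genotypes 10 of 10 columns correlated best with the column of the adjoining replicate number (1 with 2, 3 with 4, and so on), with partner correlations of 0.104 to 0.708 in WT and -0.0591 to 0.274 in atpc1-1, and none above 0.0562 or -0.0742 with any other column. By the rule set before the data were examined, the 2 columns of each pair were averaged on the log2 scale and counted as 1 replicate, so that each genotype has 5 replicates, called 1 to 5 here. The labels do not say that columns of a pair share an RNA sample, nor that the 5 replicates came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

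Values were computed from the deposited intensities as log2, with no pseudocount and with 0 treated as missing. Column medians lay up to 60.9% from their mean, beyond the 10% set in advance for keeping the deposited scale, so columns were quantile normalised with limma 3.58.1 in R 4.3.3. Quantile normalisation gives all columns about the same distribution, so it cannot show a change shared by most rows, and it changes the values of dim rows most. A row was tested if at least 3 of 5 replicates of each genotype had a value. This kept 3298 rows and left out 141, of which 62 had fewer than 3 values in atpc1-1 alone, 57 in WT alone and 22 in both.

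Differences were fitted with limma (lmFit and eBayes, no trend, two-sided), with genotype as the only term and Benjamini-Hochberg adjustment over all tested rows. A row was called changed at an adjusted p under 0.05. Log2 differences are atpc1-1 minus WT, with the standard error of the fit. All p-values described as adjusted come from this limma fit unless another test is named. The single value of the probe for the mutated gene was also tested by an exact permutation test, two-sided. In data simulated on the same 3298 rows the fit recovered 23.9% of rows changed 2-fold, 59.7% of those changed 4-fold and 90.9% of those changed 8-fold, and 8.66% of its 127 calls were false. This was 1 draw with only 67, 67 and 66 rows changed by these folds. Its rows were independent, its genotype shift was the same at all intensities, and its zeros did not follow the simulated level. The rates are therefore not the error rates of the real calls.

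Gene names came from the array platform's annotation, updated through RefSeq's gene table of assembly TAIR10.1, which was used for names only. Of the probes, 692 had 1 gene, 870 several and 1877 none. RefSeq held 690 of the 692. No gene is named from a probe with several genes, except that the probe listing ATPC1 together with ATPC2 is described as such. No coordinates are given, because the sources name no build.

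Before the data were examined, 18 gene lists with 296 genes were fixed for a chloroplast ATP synthase mutant and green tissue. Only 17 of these genes had a tested row of their own. The list of plastid ribosomal proteins alone reached the minimum of 3 measured members. The lists of the chloroplast ATP synthase, photosynthetic electron carriers, carotenoid and MEP pathway, photorespiration, plastid proteases and chaperones, plastid protein import and thylakoid targeting, starch and plastid sugar metabolism, stress and flavonoid genes, and non-green tissue markers had no tested row listing a single gene. A further 7 lists (thylakoid complexes and their assembly, Calvin cycle and stromal redox enzymes, pigment and tetrapyrrole enzymes, plastid gene expression factors, fibrillins, cell wall glycosyl hydrolases of family 9, and reproductive-organ regulators) were written after the gene names of the annotation had been read, but before any gene's values were. Lists were tested against all other rows with limma's cameraPR on the moderated statistics, with a preset correlation of 0.01 between genes, because camera itself, the test fixed in advance, takes no missing values. The p-values were adjusted over the 8 lists with at least 3 measured members. As alternatives, the correlation was estimated within each list, and fry was run on rows with values in all replicates.

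The rule for named genes, fixed in advance, took ATPC1 and the other measured members of the ATP synthase list, the 6 largest rises and 6 largest falls among called rows with 1 gene whose atpc1-1 replicates all lay on the same side of the WT mean, and, for each list with at least 3 measured members, the 2 with the smallest p and the called member that moved most against the list. Other members of the fixed lists are named because so few were measured. Called members of the added lists, and the called genes with a symbol given among the other observations, were chosen after their values were seen. Which named genes entered the table of alternatives was narrowed after the first results.

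Alternatives set before the data were examined were other scalings (deposited scale, median centring, mean scaling, cyclic loess), a pseudocount of 0.0323, zeros set to the lowest positive value of a column, removal of the dimmest rows, all 10 columns as replicates with and without the pair as a random block, a replicate block, a trended robust variance, array weights, stricter thresholds and leaving out each replicate. Quantile normalisation with zeros ranked and a test restricted to rows above 0 in all columns were added after seeing the data.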

Results

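The data compare gene expression between WT Arabidopsis and atpc1-1, a mutant that per the labels lacks the γ subunit of the chloroplast ATP synthase, the thylakoid enzyme that makes ATP from the proton gradient of photosynthesis. The question the comparison addresses is which nuclear transcripts differ when this complex is missing. Each genotype had 10 array columns, averaged to 5 replicates in pairs of adjoining numbers. Each column correlated best with its partner, but partner correlations were lower in atpc1-1 (-0.0591 to 0.274) than in WT (0.104 to 0.708). Of 3439 rows, 3298 could be tested, 665 of them with a single annotated gene. Median intensity per column was 0.339 to 0.493 in WT and 0.130 to 0.224 in atpc1-1 on the deposited linear scale, and log2 values after quantile normalisation are used throughout.

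ATPC1 itself had no probe of its own. The single probe whose annotation lists ATPC1 also lists ATPC2, and its log2 intensity was -1.28 ± 0.52 (SD, n = 5) in WT and -1.10 ± 0.75 (SD, n = 5) in atpc1-1. The WT replicates 1 to 5 stood at -2.20, -1.11, -1.21, -0.92 and -0.98, and the atpc1-1 replicates at 0.04, -1.10, -1.79, -1.75 and -0.92. The difference of 0.18 (SE 0.39) was within the replicate spread (limma adjusted p = 0.759; exact permutation p = 0.675 over 252 relabelings, two-sided), and it stood at -0.11 without atpc1-1 replicate 1, at -0.81 on the deposited scale, and at -1.20 with both (SE 0.33, limma adjusted p = 0.0104), where the median of all rows was -1.24. Which of the genes the probe reports, and whether it lies in a part of ATPC1 removed by the mutation, are not given in the sources used here. The probe therefore checks nothing about the labels, and the genotypes rest on the labels alone.

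Of the photosynthesis genes on the lists fixed in advance, PRK and PSBY rose in atpc1-1 and the others did not pass the test. PRK, the phosphoribulokinase of the Calvin cycle, rose 3.21-fold, from -0.54 ± 0.41 to 1.15 ± 0.56 on the log2 scale (SD, n = 5 each; log2 difference 1.68, SE 0.32, limma adjusted p = 0.00651). PSBY, a small protein of photosystem II, rose 2.06-fold, from 0.25 ± 0.17 to 1.29 ± 0.17 (log2 difference 1.04, SE 0.21, limma adjusted p = 0.00781). In both genes all 5 atpc1-1 replicates lay above the WT mean, and both rises were called at an adjusted p under 0.05 under every alternative setting and with each replicate left out. PSAN of photosystem I, PSBW of photosystem II and the antenna gene LHCB1.5 did not pass the test, with log2 differences of -0.04, -0.26 and -0.18. All 3 had positive values under median centring, of 1.08, 1.61 and 1.68, with limma adjusted p-values of 0.0188, 0.00245 and 0.0186, and PSBW also passed under mean scaling at 0.59. SBPASE, the sedoheptulose-bisphosphatase of the Calvin cycle, was at -1.04 (SE 0.44, limma adjusted p = 0.105) and passed on the deposited scale at -2.17, with mean scaling at -2.02 and over rows above 0 in all columns at -0.96 (limma adjusted p = 0.0455). The median of all rows in these settings, in that order, was -1.22, -1.08 and -0.03.

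**Figure D1:**
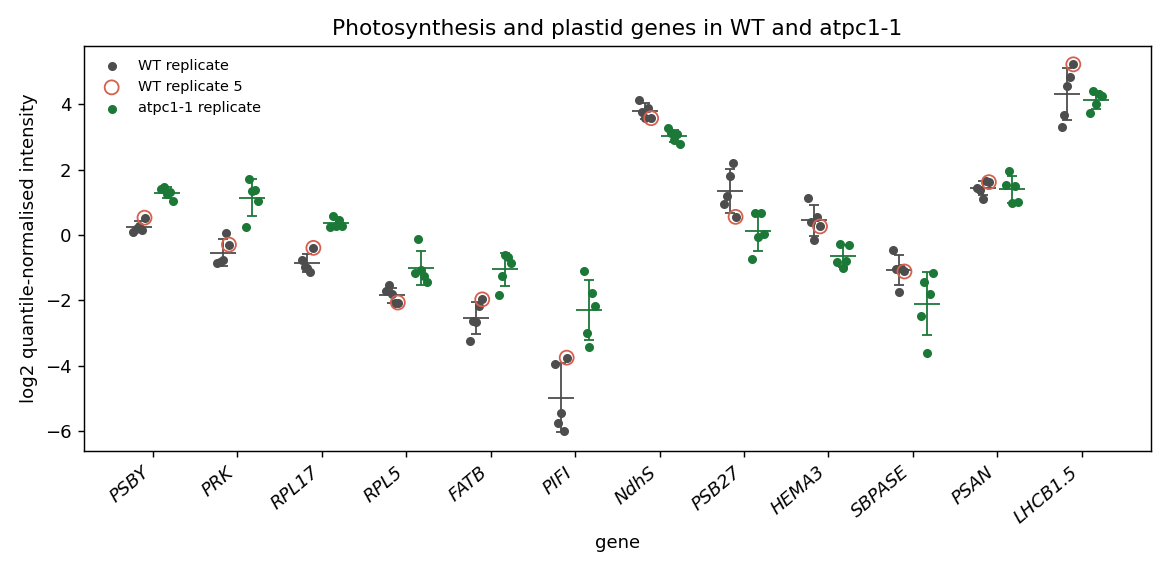
Log2 quantile-normalised intensity (vertical axis) of 12 photosynthesis and plastid genes (horizontal axis) in the 5 WT and 5 atpc1-1 replicates, each point a replicate, with mean and SD bars and WT replicate 5 ringed. PSBY, PRK and RPL17 were higher in all 5 atpc1-1 replicates than the WT mean, while PSAN and LHCB1.5 overlapped between genotypes, with log2 differences of -0.04 and -0.18 that turned to 1.08 and 1.68 under median centring; NdhS likewise turned from -0.76 to 0.81.

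Plastid ribosomal proteins were the only list fixed in advance with enough measured members. Of its 6 measured genes 2 were higher, 0 were lower and 4 did not pass, and 3 were higher when adjusted over the list alone. RPL17, a protein of the large plastid ribosomal subunit, rose by a log2 difference of 1.23 (SE 0.23, limma adjusted p = 0.00558), from -0.86 ± 0.29 to 0.38 ± 0.15 (SD, n = 5 each), and this call at an adjusted p under 0.05 held under every alternative. RPL29, also of the large subunit, rose by 3.88 (SE 0.94, limma adjusted p = 0.0193), but it was above 0 in only 4 of 10 WT columns and 5 of 10 atpc1-1 columns. RPL5 stood at 0.83 (limma adjusted p = 0.0521), RPS6 at 0.75, RPS10 at 0.04 and RPL34 at -0.54. RPL5 and RPS6 had negative values on the deposited scale, of -0.29 and -0.73, as had RPS10 at -0.97, which passed as lower there. The median of all rows there was -1.22 and 1896 of 3298 rows were called lower, so RPL5, RPS6 and RPS10 lay above the typical row. RPL34 was at 0.68 in quantile normalisation with zeros ranked. It passed as lower at -2.17 on the deposited scale and -2.02 with mean scaling (limma adjusted p = 0.0248 and 0.0358), where the medians of all rows were -1.22 and -1.08. RPS6 passed as higher with a pseudocount at 1.07, with all 10 columns at 0.97, with zeros ranked at 1.36 and without atpc1-1 replicate 1 at 1.24. RPL5 passed as higher under 11 other settings, among them median centring at 0.88 and cyclic loess at 1.01, and also without atpc1-1 replicate 5 at 0.94 (limma adjusted p = 0.0486). The list's median was 0.79, which is 0.98 above the median of all rows (-0.19). The set test against all other rows gave p = 0.0178 with limma's cameraPR, an adjusted p of 0.142 over 8 lists, and an adjusted p of 0.121 with an estimated correlation. That estimate, held at 0 or above, was 0 for this list, which is less strict than the preset 0.01. The shift of the list thus did not pass after adjustment over 8 lists, 7 of them added later. Among the lists fixed in advance it was the only list tested, so the p of 0.0178 stands there without adjustment. The cameraPR p was 0.0740 with median centring. With fry, which tests against no change, p was 0.0125 (unadjusted).

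Single measured members of other fixed lists also rose. FATB, the acyl-ACP thioesterase that releases saturated fatty acids in plastids, rose 2.83-fold (log2 SE 0.33, limma adjusted p = 0.0107). ATP16, the δ subunit of the mitochondrial ATP synthase, rose by 1.46 (SE 0.48, limma adjusted p = 0.0473), a call that was lost in 8 of the fits with a replicate left out. On the deposited scale, where the median of all rows was -1.22, neither was called, at 0.38 and 0.03. CHLM and CHLP, enzymes of chlorophyll synthesis, did not pass at -0.49 and -0.59, nor did the peroxiredoxin PRXIIE at -0.60. CHLM was called on the deposited scale at -1.90, against that median of -1.22, and CHLP stood at 0.69 under median centring (limma adjusted p = 0.0778). CHLP was called lower, at -0.59, with all 10 columns as replicates, with the pair as a random block and with a trended robust variance.

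Within the added list of thylakoid complexes and their assembly, 3 of 12 measured genes rose, 2 fell and 7 did not pass, and adjusted over the list alone 3 were higher and 3 lower. Besides PSBY, the rises were PIFI at 2.69 (SE 0.56, limma adjusted p = 0.00902), which acts in chlororespiratory electron transport, and CCB3 at 3.30 (SE 1.05, limma adjusted p = 0.0473), an assembly factor of the cytochrome b6f complex. NdhS, a subunit of the chloroplast NADH dehydrogenase-like complex, fell by 0.76 (SE 0.22, limma adjusted p = 0.0302), and PSB27, which acts in photosystem II assembly and repair, fell by 1.22 (SE 0.38, limma adjusted p = 0.0397). These members were named after their values were seen. The NdhS difference turned to 0.81 (limma adjusted p = 0.0347) under median centring, and the calls of NdhS, PSB27 and CCB3 were each lost in 7 fits with a replicate left out. PSB27 stood at -0.32 under median centring (limma adjusted p = 0.535). Its call was also lost with cyclic loess and with zeros set to the lowest positive value. CCB3 was above 0 in 5 of 10 WT and 4 of 10 atpc1-1 columns. PIFI was not called on the deposited scale (1.18, limma adjusted p = 0.0880) or with mean scaling (1.33, limma adjusted p = 0.0674). As a set the list did not differ from other rows (cameraPR p = 0.568). For change in either direction fry gave a mixed p of 4.9e-06, but it tests against no change, and 24.5% of all tested rows were called. The fry mixed p was also under 0.05 for plastid ribosomal proteins (0.00374), Calvin cycle and stromal redox enzymes (0.0163) and pigment and tetrapyrrole enzymes (0.0406). It is therefore not particular to this list. The list's distance from the median of all rows depended on scaling, at 1.00 on the deposited scale (cameraPR p = 0.00902), 1.00 with median centring (p = 0.00974) and 1.00 with mean scaling (p = 0.00825), all unadjusted over lists, against 0.0580 here. These scalings differ from one another only by a constant per column, so they are not separate results. On the deposited scale the brightest rows stood at -0.14 against -1.22 over all rows. PSBW, LHCB1.5 and NdhS were bright (WT means 5.48, 4.32 and 3.79), while PIFI and CCB3 were dim. Whether the distance follows brightness was not tested. With cyclic loess and with zeros ranked the set test did not pass, as in the main fit.

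In the added list of pigment and tetrapyrrole enzymes 2 of 5 measured genes fell and 3 did not pass. HEMA3, an isoform of the glutamyl-tRNA reductase that opens tetrapyrrole synthesis, fell by 1.09 (SE 0.29, limma adjusted p = 0.0213), and Z-ISO, the ζ-carotene isomerase of carotenoid synthesis, fell by 1.16 (SE 0.38, limma adjusted p = 0.0485). The HEMA3 call was lost under median centring (-0.49) and without WT replicate 4. The Z-ISO call was lost in 8 fits with a replicate left out and under 7 other settings, among them cyclic loess and array weights. Among Calvin cycle and stromal redox enzymes PRK was the 1 called gene of 7, and 6 did not pass. Of 5 fibrillins, proteins of plastid lipid droplets and thylakoids, FBN6 fell 2.83-fold (log2 SE 0.42, limma adjusted p = 0.0286), and 4 did not pass. The FBN6 call was lost in 5 fits with a replicate left out, with the replicate block and with the pair as a random block. It was also lost with a pseudocount, with zeros set to the lowest positive value and with zeros ranked. FBN6 was above 0 in 10 of 10 WT columns and 7 of 10 atpc1-1 columns. None of 6 plastid gene expression factors, 3 cell wall glycosyl hydrolases of family 9 or 5 reproductive-organ regulators were called. The cameraPR p-values of these lists, in the order given, were 0.172, 0.990, 0.825, 0.523, 0.744 and 0.510, and no list passed after adjustment over 8 lists. The family 9 list held 4 genes, of which 3 were tested. GH9B16, of the same family, had too few atpc1-1 values for a test, with 4 of 10 atpc1-1 columns above 0 against 10 of 10 in WT. With fry, which tests a list without setting it against other rows, the pigment and tetrapyrrole enzymes were lower (p = 0.00296, unadjusted).

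The 6 largest falls among genes with a probe of their own were above 0 in all 10 WT columns. AT5G39980, which encodes a pentatricopeptide repeat protein, fell by 3.73 on the log2 scale, from 0.88 ± 1.58 to -2.85 ± 0.55 (SD, n = 5 each; SE 0.65, limma adjusted p = 0.00555). AT5G17630, the plastid xylulose 5-phosphate translocator, fell by 3.37, from 1.75 ± 1.12 to -1.62 ± 0.68 (SD, n = 5 each; SE 0.53, limma adjusted p = 0.00337). AT4G35660 fell by 3.59 and AT4G18180 fell by 3.56. AT3G50270, of the HXXXD acyltransferase family, fell by 3.17, and AT3G04210, a TIR-NBS protein, fell by 3.04. All 6 were lower than WT on every scaling, and AT3G50270 lost its call without WT replicate 1, 2, 3 or 4 and with zeros set to the lowest positive value. In all 6, WT replicate 5 lay below the other WT replicates, at -1.80 in AT5G39980, -0.79 in AT4G35660, -1.43 in AT4G18180, -0.23 in AT5G17630, -2.71 in AT3G50270 and -1.55 in AT3G04210. That replicate lay within the atpc1-1 range in AT4G35660, AT4G18180 and AT3G50270, and above it in AT5G39980, AT5G17630 and AT3G04210.

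By contrast, the 6 largest rises all started near the floor in WT, with WT means between -8.36 (AT3G47080) and -6.86 (AT2G45500). AT3G47080 rose by 5.18 (SE 0.63, limma adjusted p = 0.00315), RPL29 by 3.88, AT5G65360, a histone H3.1 gene, by 3.81 (SE 0.68, limma adjusted p = 0.00581), AT2G45500 by 3.71, AT1G20130 by 3.50 and CCB3 by 3.30. These differences compare positive values only. AT3G47080 was above 0 in 5 of 10 columns of each genotype, and AT5G65360 in 4 of 10 WT and 6 of 10 atpc1-1 columns. AT2G45500 and CCB3 were above 0 in fewer atpc1-1 than WT columns, 6 against 7 and 4 against 5. With zeros set to the lowest positive value the AT3G47080 call was lost (limma adjusted p = 0.0515), and on at least 1 other scaling those of RPL29, AT2G45500, AT1G20130 and CCB3 were lost.

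Over all rows, 337 were called higher and 471 lower in atpc1-1, 24.5% of those tested, with a median change of 2.79-fold among the higher and 2.80-fold among the lower. Rows with 1 gene gave 56 higher and 98 lower of 665. The split depended on scaling: 126 higher and 1896 lower on the deposited scale, 150 and 1666 with mean scaling, 497 and 403 with median centring, 310 and 293 with cyclic loess, and 716 and 361 with quantile normalisation and zeros ranked, the last added after seeing the data. The median of all rows moved with it, from -0.19 to -1.22, -1.08, -0.05, -0.16 and 0.17, so the number of genes lower in atpc1-1 in absolute terms is not settled by these data.

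**Figure D2:**
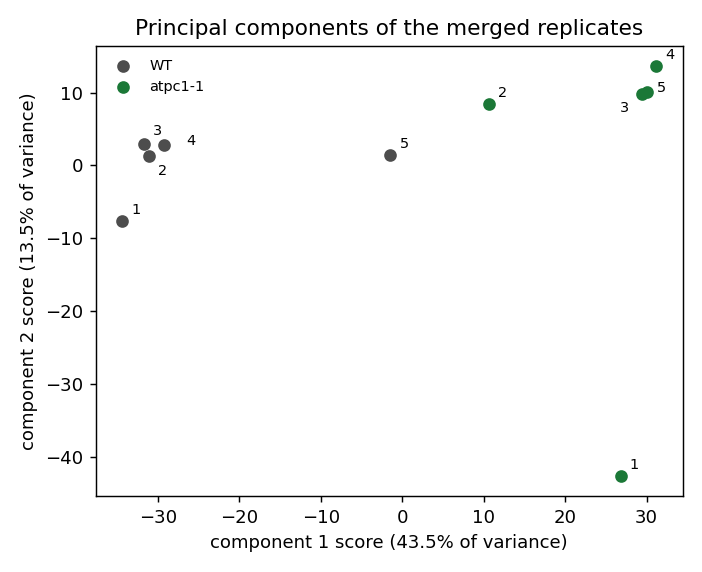
Scores of the 5 WT and 5 atpc1-1 replicates (numbered points) on principal components 1 and 2 of 2712 rows measured in all replicates, with 43.5% and 13.5% of the variance. WT replicates 1 to 4 lie between -34.4 and -29.3 on component 1, WT replicate 5 at -1.45, and the atpc1-1 replicates between 10.6 and 31.1.

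Replicates differed within WT. WT replicates 1 to 4 correlated with one another at Spearman rho 0.883 to 0.953 across 2712 genes or probes, which are not independent, and replicate 5 with them at 0.810 to 0.828, against 0.765 to 0.842 with the atpc1-1 replicates. Without WT replicate 5 the counts were 417 higher and 540 lower. Without WT replicate 1, 2, 3 or 4 they were 214, 194, 203 and 215 higher and 262, 259, 258 and 263 lower.

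**Figure D3:**
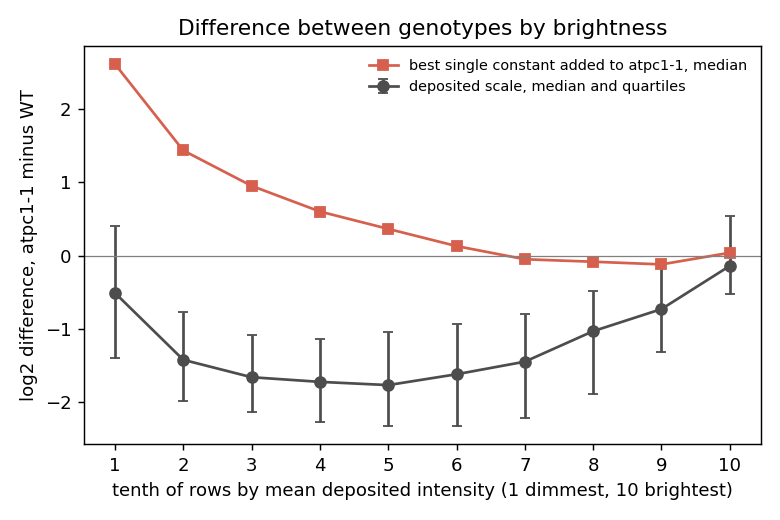
Median log2 difference, atpc1-1 minus WT, on the deposited scale (circles, bars from the lower to the upper quartile) in 10 groups of rows ordered by mean deposited intensity, and the median after a constant of 0.39, the best fit to these same data, was added to the atpc1-1 values (squares). The deposited difference was -0.51 in the dimmest group, -1.77 in group 5 and -0.14 in the brightest.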

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

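Of the tests below, the splits of the replicates were set before the result was seen, and the tests of brightness, of the added constant, of WT replicate 5 and of the ATPC1 probe were chosen after; the test of the constant was divided into brighter and dimmer rows because it gave no decision undivided, the test of mislabelling replaced an earlier one and was later widened to rank correlations, and the test of the ATPC1 probe was later widened to all scalings.

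Each group tested was the replicates of 1 genotype in 1 named gene. Many of these genes were named because they changed in these data, and all share the same replicates. Of 96 groups, 10 held a replicate far from the others. About 4.80 would be expected by chance in unselected, independent groups, which these are not. Of the 10, 7 were in WT and 5 of those in WT replicate 5. In these the gap of the far replicate to its nearest neighbour, as a share of the group's range, was 0.806 for AT4G35660, 0.796 for AT4G18180, 0.820 for AT5G17630, 0.9001 for AT3G50270 and 0.803 for PRA1.B6, each time with WT replicate 5 lowest, nearest to atpc1-1. The first such pattern is that WT replicate 5 lies between the genotypes. Whether it is a mislabelled atpc1-1 sample stays open, as its values go both ways. It differs from atpc1-1 in that 87.7% of 946 rows called without it were displaced from the atpc1-1 mean toward WT replicates 1 to 4, above the 47.2% to 73.0% of the atpc1-1 replicates treated in the same way (SD 10.9). Its rank correlations with atpc1-1, 0.765 to 0.842, lie within those among the atpc1-1 replicates, 0.758 to 0.851, and those with WT replicates 1 to 4, 0.810 to 0.828, lie above the 0.588 to 0.792 between WT replicates 1 to 4 and atpc1-1. Its columns also differ from every atpc1-1 column in rows at 0 (4.01% and 4.19%, against 5.70% to 20.8%), in the share of the 50 brightest rows (31.6% and 31.8%, against 44.0% to 49.7%) and in having no value at the ceiling, but these could follow the processing of the columns and so do not decide. The earlier test, the share of rows called between replicates 1 to 4 with the same direction between replicates 5, gave 86.4% against a bound of 80%, and was replaced because an atpc1-1 replicate lying nearer WT could pass it too. A change of scale or background that keeps the order of rows is argued against by ranks, as its highest rank correlation with WT replicates 1 to 4 was 0.828 and the lowest among them 0.883. Rows called without both replicates 5 differed in the same direction between replicates 5 in 87.8% of the higher and 85.4% of the lower, but by 47.0% and 45.1% of the size. Other same-numbered replicates, held out in the same way, kept 93.0% to 112% of the size in the higher rows. In the lower rows they kept 60.8% (replicates 2) to 120%. A mixed sample, a separate growth or hybridisation batch, or WT replicates 1 to 4 sharing a feature unrelated to genotype may account for the position of WT replicate 5 and stay open, as the labels give no batch. WT replicate 5 also had the lowest column medians of WT (0.339 and 0.347), and atpc1-1 replicate 2, nearest to WT on component 1 among the mutant replicates, the highest of atpc1-1 (0.224 and 0.222).

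The second pattern is that deposited intensities were lower in atpc1-1, with a median log2 difference of -1.22 over all rows. A few bright rows holding more of the total are argued against as the whole cause, since scaling to the mean without the 50 brightest rows of each column left -0.64 (-0.68 to -0.56 with a replicate left out). A constant removed from the atpc1-1 values, such as a stronger background subtraction, may contribute in the brighter rows, where adding back 0.39 left at most 0.13 in any of the upper 5 groups. The value of 0.39 was the best-fitting constant for these same data, so the small remainder is not independent evidence. For the dimmer rows a single constant is argued against, because at least 38.2% of values in every WT column lay at or below it while at most 20.8% of rows stood at 0 in an atpc1-1 column, and with it added the dimmest group stood at 2.62. A lower RNA level of many genes in the mutant stays open and untested, since the authors' scaling is not given.

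The third pattern is that the probe listing ATPC1 and ATPC2 was not lower in atpc1-1. In that probe WT replicate 1 was far below the others, with a gap of 0.778 of the range, and atpc1-1 replicate 1 was the highest of its group. The 2 columns averaged in atpc1-1 replicate 1 differed, at 0.496 and 1.96 on the deposited scale. Every other atpc1-1 column lay between 0.113 and 0.395. Whether atpc1-1 replicate 1 alone hides a loss stays open, since without it the difference was -0.11 (SE 0.34) after quantile normalisation but -1.20 (SE 0.33) on the deposited scale and -1.06 with mean scaling. On these 2 scales the median of all rows was -1.24 and -1.10, so the probe then lay 0.0387 and 0.0394 above it. Signal from ATPC2, or a transcript of the mutant allele that still covers the probe, may account for the value and stays open, as the probe's sequence was not used here.

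The count of 808 changed rows exceeded every other split of the 10 replicates that was drawn. Of 100 splits, 1, the real one, called as many rows, and the highest of the others called 271. A chance assignment of the replicates is thus argued against, within the 100 splits drawn. All other splits mix both genotypes in each group, which widens the spread within groups and lowers their counts. The splits cannot tell genotype apart from a batch or a processing difference that went with it.

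Other single replicates far from their group were WT replicate 3 of AT2G45500 (0.842, lowest), atpc1-1 replicate 2 of RPL5 (0.718, highest), atpc1-1 replicate 1 of RPS6 (0.929, lowest) and atpc1-1 replicate 4 of SIS (0.786, lowest).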

How the results depend on the processing

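Quantile normalisation with zeros ranked and the restriction to rows above 0 in all columns were chosen after seeing the data; all other alternatives were set before. The cause of each change below was not tested, except that thresholds, fewer rows or more columns act by construction. Signal near the floor limits the comparison, since up to 20.8% of rows in an atpc1-1 column stood at 0. Higher and lower calls, 337 and 471, became 126 and 1896 on the deposited scale, 150 and 1666 with mean scaling, 310 and 293 with cyclic loess, 631 and 522 with a pseudocount, 516 and 827 with all 10 columns as replicates, 716 and 361 with zeros ranked, 342 and 311 over rows above 0 in all columns, and 91 and 105 at an adjusted p under 0.01. With a replicate left out they ranged from 194 (without WT replicate 2) to 417 (without WT replicate 5) higher and from 258 (without WT replicate 3) to 540 (without WT replicate 5) lower. Of the 808 calls, 572 were kept in the same direction on the deposited scale, 627 with median centring (3 turned), 533 with cyclic loess and 747 without WT replicate 5. The replicate numbers were not taken to pair the samples, because not every pair was over 0.1, with correlations of 0.115, 0.101, 0.024, 0.038 and 0.216 between same-numbered replicates and 3 of 5 WT replicates closest to their own number. A replicate block gave 317 higher and 415 lower calls and kept 638 of the calls. Among named genes, AT1G20130, CCB3, ATP16, Z-ISO, FBN6 and DI21 lost their calls under that block. The ATPC1 probe difference was -0.81 on the deposited scale, -0.67 with mean scaling and -0.0365 with array weights, and -0.11 (without atpc1-1 replicate 1) to 0.35 (without atpc1-1 replicate 3) with a replicate left out, and it passed in none of these taken singly. With atpc1-1 replicate 1 left out as well, it passed on the deposited scale at -1.20 and with mean scaling at -1.06 (limma adjusted p = 0.0104 and 0.0194). The median of all rows was then -1.24 and -1.10. For plastid ribosomal proteins the distance above the median of all rows was 0.70 (p = 0.0740) with median centring, 0.86 (p = 0.0733) over rows above 0 in all columns, and 0.80 to 1.23 with a replicate left out, with p = 0.0638 and 0.0532 without WT replicate 2 and 4 and just over the threshold without WT replicate 3. Thylakoid complexes lay 1.00 above the median of all rows on the deposited scale, with median centring and with mean scaling (cameraPR p = 0.00902, 0.00974 and 0.00825), which differ only by a constant per column and so are not separate results. Pigment and tetrapyrrole enzymes passed with fry, which tests against no change (p = 0.00296), but not against other rows (cameraPR p = 0.172). None of the turned list directions that follow passed 0.05. Calvin cycle and stromal redox enzymes, whose camera direction turned, had a distance of -0.0831 on the deposited scale, -0.0824 with mean scaling, -0.0882 with median centring, -0.15 with cyclic loess, 0.0175 without the dimmest rows, -0.20 with all 10 columns and with the pair as random block, -0.24 with trend, and -0.0704 over rows above 0 in all columns, and ranged from -0.41 (without WT replicate 5) to 0.0854 (without atpc1-1 replicate 3). Fibrillins turned at 0.31 on the deposited scale and with mean scaling and 0.37 with median centring, reproductive-organ regulators at 0.14 on both and 0.21 over rows above 0 in all columns. Fry, which does not test this distance, had the direction opposite to cameraPR for Calvin cycle and stromal redox enzymes (distance -0.24) and thylakoid complexes (0.0580). With a replicate left out fibrillins turned without atpc1-1 replicates 4 and 5 (0.41 and 0.44) and glycosyl hydrolases of family 9 without 2 and 5 (0.13 and 0.31), and the lowest distances, not turned, were 0.41 and -0.49 without atpc1-1 replicate 1, with the highest for fibrillins 0.68 without WT replicate 5. Among named genes, 918 of the recomputed values kept direction and side of the threshold, 135 lost the call, 26 gained one and 41 turned. Turned values with median centring were 1.08 for PSAN, 1.61 for PSBW, 1.68 for LHCB1.5, 0.69 for CHLP, 0.81 for NdhS, 0.26 for XERICO and 0.95 for CCL. On the deposited scale they were 0.44 for PSBW, 0.52 for LHCB1.5, -0.29 for RPL5, -0.73 for RPS6, -0.97 for RPS10 and -0.0064 for CKS, and with mean scaling 0.0631 for PSAN, 0.59 for PSBW, 0.66 for LHCB1.5, -0.14 for RPL5, -0.59 for RPS6 and -0.83 for RPS10. The medians of all rows on the deposited scale and with mean scaling were -1.22 and -1.08. PSAN was also at 0.0145 with cyclic loess, 0.12 with a pseudocount, with zeros at the lowest value and with zeros ranked, 0.0186 without the dimmest rows, 0.0083 with array weights and 0.0931 over rows above 0 in all columns. CHLM was at 0.0131 without the dimmest rows and 0.12 with zeros ranked, and RPL34 at 0.12 with a pseudocount, 0.26 with zeros at the lowest value and 0.68 with zeros ranked. With a replicate left out, PSAN ranged from -0.18 (without atpc1-1 replicate 2) to 0.0584 (without atpc1-1 replicate 3), LHCB1.5 from -0.44 (without WT replicate 1) to 0.0448 (without WT replicate 5), CHLM from -0.87 (without atpc1-1 replicate 4) to 0.0717 (without atpc1-1 replicate 1) and RPS10 from -0.13 (without WT replicate 1) to 0.28 (without atpc1-1 replicate 3).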

Other observations

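Outside the lists, 15 called genes carried a symbol of their own, 6 higher and 9 lower in atpc1-1, and all were chosen after their values were seen. CYN, the cyanase that breaks down cyanate, rose by 2.099 on the log2 scale (SE 0.35, limma adjusted p = 0.00456), and CUTA, a plastid protein related to bacterial copper tolerance factors, rose by 1.49 (SE 0.34, limma adjusted p = 0.0119); both were called at an adjusted p under 0.05 under every alternative. LpxA and CKS, which act in the synthesis of lipid A and of the sugar KDO, were higher by 1.32 and 1.96. LpxA lost its call in 5 fits with a replicate left out. CKS was above 0 in 9 of 10 WT columns but only 3 of 10 atpc1-1 columns, so its difference compares positive values only. It stood at -0.0064 on the deposited scale. The CKS call was also lost under 6 other settings, among them a pseudocount, at 0.46 (limma adjusted p = 0.299). TPP2, a tripeptidyl peptidase, and IQD22 were higher by 1.397 and 2.28, and neither was called on the deposited scale.

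Among the lower genes, APTX, related to the DNA repair protein aprataxin, fell by 2.94 (SE 0.67, limma adjusted p = 0.0123), PRA1.B6 fell by 2.60, and PPDK, the pyruvate orthophosphate dikinase, fell by 1.12 (SE 0.29, limma adjusted p = 0.0211); these 3 calls at an adjusted p under 0.05 held under every alternative in which the gene was tested, and APTX and PRA1.B6 could not be tested over rows above 0 in all columns. LAS, a regulator of axillary shoots, fell by 1.33 and lost its call with cyclic loess. XERICO, a RING protein of abscisic acid homeostasis, fell by 1.02 (limma adjusted p = 0.0129), but it stood at 0.26 under median centring, which did not pass. CCL fell by 0.97, but it was called higher under median centring, at 0.95 (limma adjusted p = 0.0326), and was not called on the deposited scale or with mean scaling. SIS fell by 1.61, DI21 by 1.06 and MAMI by 0.90. Their calls were lost in 2, 7 and 4 fits with a replicate left out, and under 4, 5 and 2 other settings. MAMI stood at -0.04 under median centring (limma adjusted p = 0.902).

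Some rows could not be tested because too few atpc1-1 replicates had a value. GH9B16, AT5G48130, AT1G32220 and AT5G38360 were above 0 in all 10 WT columns and in only 4, 4, 3 and 2 of 10 atpc1-1 columns, with WT median intensities of 0.347, 0.102, 0.307 and 0.185 on the deposited scale. Since more rows stood at 0 in atpc1-1 columns in general, these counts are values only. AT1G68160 was at 0 in all 10 WT columns and above 0 in 7 atpc1-1 columns, at a median of 0.0192.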
